A study of Mus musculus with 2 samples.

How the data were processed

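DP thymocytes of Bcl11bF/FCD4Cre/Tcra-/- mice and of TCRa-/- mice were compared on 2 arrays of a mouse 2-colour oligonucleotide design, each with 1 sample of either genotype. The deficient sample carried Cy5 and the control Cy3 on both arrays, with no array in the reverse orientation. According to the labels, RNA was taken up in trizol and cleaned on columns, amplified with a linear Agilent kit and labelled with a Kreatech ULS kit. The labels do not say how many mice gave each sample, how DP cells were selected, or which part of Bcl11b is deleted.

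The authors read the scans with Agilent Feature Extraction 9.5.3.1. The deposited mean signals and local background signals are in units of scanner intensity with no correction, per the file headers. The deposited processed signals are also intensity values, which Feature Extraction corrected for background and spatial trend and normalised between dyes, with substitutes in place of very dim signals. The deposited log ratio is the log10 of the processed Cy5 signal over the processed Cy3 signal. The deposited value table of the series holds no stated unit, and its values equal that log10 ratio to within 0.005 at every spot, with a median of 0 on each array. Probe positions are those of the mm8 build printed in the array files.

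Each array held 45018 spots, 43379 of them not controls, and 153 negative controls. Median signals were 1158 and 1251 in the deficient channel and 842 and 848.0 in the control channel of replicates 1 and 2. Negative controls had medians of 923 and 1036 in the deficient channel and 696 and 732 in the control channel, while the local background was 52 and 52, and 47 and 48. One deficient spot per array and no control spot was saturated. Spots marked by Feature Extraction as non-uniform or outlying were left out, 108 on replicate 1 and 116 on replicate 2.

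Signals were background-corrected by the normexp method with an offset of 50 on the local background and normalised by loess within each array, with weight 0 for controls, in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. The spots of each probe were averaged. Of 41174 probes, 21538 were kept as well above background in the deficient channel on both arrays or in the control channel on both. Probes took current gene symbols from the reference gene table by accession (24490 probes), symbol (6234) or synonym held by 1 gene (2391), and 8059 kept the name in the array file. Each gene was represented by its brightest kept probe, which left 14922 genes, 4728 of them with more than 1 probe. Other probes of these genes numbered 6616, and 69.6% had the same sign of the mean ratio.

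Values are log2 ratios of deficient over control. The mean of the 2 arrays was tested against 0 with limma's moderated test, which had 1 residual degree of freedom and a fitted prior of 2.50 degrees of freedom and SD 0.117, and p values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. SE values are moderated by limma over all genes. Genes at least 2-fold changed in the same direction on both arrays were counted beside the test. Those of opposite direction were counted as a measure of noise between arrays. Bias that follows dye goes the same way on both arrays, so the opposite count cannot show it. Where a gene was not well above background in one group on either array, its fold is given as a bound from the signals. In simulated data of 14922 genes with the fitted spread, the test recovered 61.1% of 2-fold and 94.7% of 4-fold changed genes at the threshold, with a mean of 9.5 false calls, and a list shifted by 0.4 was called in 10 of 10 simulations. The simulation drew genes independently and changed 200 of them, and 5.20% of unchanged genes had an unadjusted p under 0.05. In the data 4355 genes did, and none of the 163 genes at least 2-fold changed was called. The simulated rates are therefore not the power of the test in these data.

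The normexp correction took a background of 447 and 479 in the deficient channel and 358 and 374 in the control channel, less than the negative controls, so ratios of dim genes are compressed. In simulated signals a true log2 ratio of 2 was recovered as 1.02 at a mean log2 intensity under 10, 1.54 from 10 to 11, 1.78 from 11 to 12, 1.90 from 12 to 14 and 1.98 from 14. Values from the processed signals are therefore given beside some of the values, and the plot of ranked genes shows them for each gene in it.

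Lists were tested with limma's camera at a preset correlation of 0.01, with p values adjusted over all 29 lists. Members were also adjusted over the list alone. Since 4355 of 14922 genes had an unadjusted p under 0.05, members of any list can pass that way. Counts of such members therefore do not by themselves set a list apart from other genes. Camera was repeated with an estimated correlation, which gave adjusted p of at least 0.779 for every list. That version rests on the 1 residual degree of freedom, so it could hardly call any list. For the NK and innate-like list the estimated correlation was -0.048, below the preset 0.01, yet camera's unadjusted p rose from 5.65e-09 to 0.0989. The loss of calls there does not show that correlation between genes undoes them. Limma's fry, which asks whether a list's genes move one way on balance, gave a smallest adjusted p of 0.106. Camera and fry gave opposite directions for the BCL2 family and caspase genes and for the trafficking and adhesion receptors, neither of which passed. The lists covered mature and DP stage thymocyte genes, T cell receptor signalling and its induced genes, NK and innate-like effector, lysosome, SLAM, BCL2 family and caspase, p53, cell cycle, interferon, MHC class I, trafficking, cytokine receptor, T lineage factor, early thymocyte, ribosomal, oxidative phosphorylation and immediate early genes. Marker lists of 10 other cell types were added.

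Lists, tests, alternatives and the rule for naming genes were fixed before the data were examined, save those said to be chosen later. The rule took Bcl11b, then the 12 highest and the 12 lowest genes by the smaller absolute ratio of the 2 arrays, then up to 4 members of each list by smallest p. Places left by genes past the threshold went to genes at least 2-fold changed on both arrays, so all 24 missed the test. The values of 1 of these genes are not reported here. Genes known only by an accession or clone name were left out, which removed 1 clone transcript that stood between Cxcr5 and Sting1.

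The alternatives were no background subtraction, Agilent processed signals, the value table of the series, median centring in place of loess, no filter on dim probes, a filter on both channels, removal of saturated probes, the mean of a gene's probes, every probe tested separately, an intensity trend or robust fit in limma, separate-channel limma after Aquantile normalisation with an intraspot correlation of 0.380, fold thresholds of 1.5 and 3, an estimated correlation in camera, and each replicate left out. Centring on the running median of 101 genes of like intensity, removal of genes with a mean log2 intensity of at least 16, and the other Bcl11b probe were added after the data were seen.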

Results

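RNA of double-positive (DP) thymocytes was compared on 2 mouse 2-colour oligonucleotide arrays. On each array, cells of Bcl11bF/FCD4Cre/Tcra-/- mice, in which Cre expressed from Cd4 control sequences acts on a floxed Bcl11b gene, carried Cy5, and cells of TCRa-/- mice carried Cy3. Bcl11b is a zinc finger transcription factor of T lineage cells, and without Tcra thymocytes form no alpha beta T cell receptor and stop before selection. The labels name the arrays biological replicates 1 and 2, so each group had 2 samples and each array gave 1 ratio of Bcl11b-deficient over control. Of 43379 spots that were not controls, 56.5% and 50.5% were well above background in the deficient channel of replicates 1 and 2, and 51.7% and 50.6% in the control channel. After the filter, 14922 genes were tested, and 2 arrays limit the precision of every value below. Values are mean log2 ratios ± SE (limma, n = 2 arrays) unless stated.

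The comparison asks what loss of Bcl11b alters in DP cells that have not met selection. The control label names neither Cre nor a floxed Bcl11b gene, so an effect of Cre cannot be told apart from loss of Bcl11b. Cxcr5, a chemokine receptor of follicular homing, was higher in the deficient cells by 3.68 and 5.40 on the 2 arrays (mean 4.54 ± 0.46), over a control signal well above background on 1 of them. Sting1, the adaptor of cytosolic DNA sensing, followed at 3.17 ± 0.31, the NK receptor gene Klrb1c at 2.87 ± 0.25, and Itgb7, an integrin subunit of gut homing, at 2.66 ± 0.32. Ankrd6 at -2.53 ± 0.23, the sodium channel subunit gene Scn2b at -2.10 ± 0.12 and Il34, which encodes a ligand of the CSF1 receptor, at -1.60 ± 0.07 were lower on both arrays. As sets, NK and innate-like effector genes (median 0.56), cell cycle genes (0.41) and ribosomal protein genes (0.45) rose, and genes of the DP stage (-0.29) fell, by limma's camera test with a preset correlation. The ribosomal call was lost after centring on genes of like intensity (0.01, camera adjusted p = 0.705), a centring that these genes partly set themselves. The DP stage call was lost with median centring (0.02, camera adjusted p = 0.488), though camera's direction stayed down. Centring on genes of like intensity gave the DP stage list -0.45 (camera adjusted p = 3.84e-06). None of these sets passed with an estimated correlation (adjusted p = 0.779 for each). That version rests on 1 residual degree of freedom, so it could hardly call any list and does not decide whether correlation between genes undoes the calls. No single gene passed limma's test over all genes in the main setting. Separate-channel limma called 1282 genes, median centring 982, processed signals 213 and the value table of the series 124.

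Bcl11b itself was measured by 2 probes on chromosome 12 (mm8 build). The brighter probe, at 108358529 to 108358588, gave -1.40 on replicate 1 and -0.28 on replicate 2, with a mean of -0.84 ± 0.31 (limma adjusted p = 0.188). These ratios put the deficient cells at 37.9% and 82.6% of the control level. The other probe, at 108363444 to 108363503, gave -1.37 and -2.16, with a mean of -1.76 ± 0.22 (limma adjusted p = 0.0964), or 38.7% and 22.4% of control. The probes thus read alike on replicate 1 and far apart on replicate 2, where they parted in both channels. Processed control signals on replicates 1 and 2 were 14964 and 8190 for the brighter probe, and 15395 and 15984 for the other. Processed deficient signals were 5868 and 6924 for the brighter probe, and 6095 and 3573 for the other. Where the probes lie relative to the deleted part was not examined, since the labels do not give that part.

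The 12 genes ranked highest all missed the test, with limma adjusted p from 0.0668 to 0.0777. Of them, 12 passed with median centring, 12 with separate-channel limma and 6 with processed signals. These settings used the same 2 arrays, so their calls are not independent support. Median centring also does not correct ratios by intensity, and over all genes it called 877 higher and 105 lower. In mm8, Cxcr5 lay at 44262983 to 44263042 on chromosome 9 and Sting1 at 35860012 to 35860071 on chromosome 18. Klrb1c lay at 128744204 to 128744263 on chromosome 6. Agilent's processed signals gave 4.24 and 9.55 for Cxcr5, the second over a dim control signal. Klrb1c read 2.42 and 3.32, and the processed signals gave 4.09. Heyl, a Notch-responsive transcriptional repressor, was at least 3.97-fold higher by its brighter probe, whose control signal was not well above background on either array. Its other probe, well above background in both channels, read 0.50. Camk2b, a calcium-dependent kinase subunit, stood at 2.27 ± 0.21. Rgs3 (2.37 ± 0.22), the histone genes H2aj (2.04 ± 0.08) and H2ac10 (1.99 ± 0.07), Fau (2.01 ± 0.10) and Ptprz1 also belonged to this group. Ptprz1, whose deficient signal was saturated on both arrays, read 1.97 with loess and 1.48 with processed signals. These last 4 lay among the 77 genes with a mean log2 intensity of at least 17, whose medians were 1.06 and 1.07 on the 2 arrays. After centring on genes of like intensity they read 1.28 for H2aj, 1.28 for H2ac10 and 1.11 for Fau, and the ratio of Ptprz1 was lower too. Other probes of 3 of these genes read far lower, at 0.14 for H2aj, 0.14 for H2ac10 and -0.26 to 0.80 for the 4 others of Rgs3. Cxcr5, Sting1, Klrb1c, Itgb7, Camk2b, Fau and Ptprz1 had no other kept probe. With processed signals another probe was the brightest for Rgs3 and H2ac10, and both turned negative, at -0.36 and -0.26.

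The 12 genes ranked lowest also missed the test, with limma adjusted p from 0.0668 to 0.0820, although 12 passed with median centring, 11 with separate-channel limma and 8 with processed signals. Ankrd6 lay at 33132656 to 33132715 on chromosome 4, Scn2b at 44880857 to 44880916 on chromosome 9 and Il34 at 113628612 to 113628671 on chromosome 8. Il34 read -1.61 and -1.60 on the 2 arrays. Smoc1, which encodes a secreted calcium-binding protein, averaged -2.42 ± 0.32 and its deficient signal was well above background on 1 array, with -2.84 and -6.25 from the processed signals. Rptoros was at least 2.15-fold lower, since its deficient signal was not well above background on either array. Ppfibp2 (-1.83 ± 0.13), Tmcc3 (-1.85 ± 0.16), Tox3 (-1.77 ± 0.15), Esrp2 (-1.57 ± 0.12), Tdrd5 (-1.54 ± 0.11), Xrra1 (-1.45 ± 0.08) and Igsf23 (-1.43 ± 0.07) made up the rest, with -2.66 for Esrp2 from the processed signals. Ankrd6, Scn2b, Smoc1, Rptoros, Il34, Tox3 and Xrra1 had no other kept probe. For Ppfibp2, Tmcc3, Igsf23, Esrp2 and Tdrd5 every other kept probe was also lower. These probes ranged from -1.90 for one probe of Tmcc3 to -0.36 for another.

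**Figure D1:**
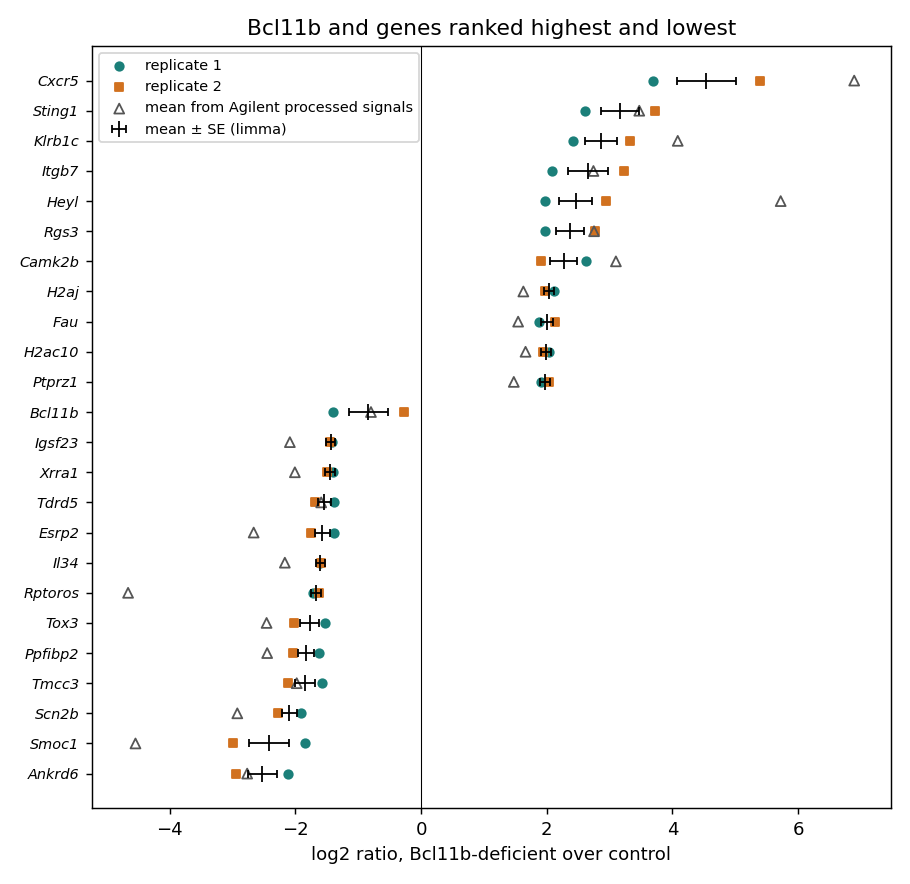
Log2 ratio of Bcl11b-deficient over control DP thymocytes for Bcl11b and the genes ranked highest and lowest that the text names, with 1 symbol per array, the mean ± SE from limma (n = 2 arrays) and a triangle for the mean from Agilent processed signals of the same probe; Heyl and Rptoros rest on a signal not well above background in 1 group, and Ptprz1 on a saturated one. Cxcr5 lies at 3.68 and 5.40 on the 2 arrays, and Bcl11b at -1.40 and -0.28.

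Genes of NK and innate-like effector cells rose as a set, with medians of 0.60 and 0.55 on replicates 1 and 2 (camera adjusted p = 5.46e-08; adjusted p = 0.779 with an estimated correlation). Of 21 measured members, 18 were higher on both arrays and 1 lower. Adjusted over the list alone, 14 passed and all 14 were higher. Of all 14922 genes, 4355 had an unadjusted p under 0.05, so here and below such counts do not by themselves set a list apart. Adjusted over all genes tested, limma called 0 of the 21 members, separate-channel limma 8 and limma on processed signals 3, all higher. The 14 included the NK receptor gene Klrd1 at 1.28 ± 0.07, the interleukin receptor gene Il2rb at 0.95 ± 0.08, and Cd160, which was at least 1.33-fold higher over a control signal not well above background. The processed signals gave this list a median of 0.92. The NK cell marker list, which shares members with it, rose too, with a median of 0.36 over 10 genes (camera adjusted p = 0.00368; 0.0664 with median centring; adjusted p = 0.779 with an estimated correlation).

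Cell cycle genes rose as a set, with medians of 0.40 and 0.49 (camera adjusted p = 1.56e-09; adjusted p = 0.779 with an estimated correlation). Of 35 genes, 29 were higher on both arrays and 2 lower, and 21 passed adjusted over the list alone, all higher. The replication licensing genes Mcm6 (1.08 ± 0.09) and Mcm3 (0.75 ± 0.09), Pcna (0.76 ± 0.09) and Birc5 (0.61 ± 0.08) were among them. Early thymocyte and Notch target genes rose, with a median of 0.42 over 16 genes, 0.26 on replicate 1 and 0.43 on replicate 2 (camera adjusted p = 0.00356; 0.0580 with median centring; adjusted p = 0.779 with an estimated correlation). In that list 8 genes passed adjusted over the list alone, all higher, with Il7r at 1.60 ± 0.09, Notch1 at 0.83 ± 0.08, Dtx1 at 0.69 ± 0.07 and Cd34 at 0.55 ± 0.08.

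Genes of the DP stage fell as a set, with medians of -0.23 and -0.31 (camera adjusted p = 0.0101, or 0.779 with an estimated correlation). Median centring in place of loess gave 0.02 (camera adjusted p = 0.488), with camera's direction still down. Running-median centring gave -0.45 (camera adjusted p = 3.84e-06) and removal of bright genes -0.35 (8.65e-05), both chosen after the data were seen. Of 24 genes, 16 were lower on both arrays and 6 higher, and adjusted over the list alone 13 passed as lower and 3 as higher. The transcription factor gene Ets2 (-1.05 ± 0.09), Arpp21 (-0.68 ± 0.07) and Tdrd5 were lower, whereas Dntt, which encodes terminal transferase, was higher at 1.58 ± 0.10. Genes of mature single positive thymocytes rose, with a median of 0.19 over 24 genes (camera adjusted p = 0.00946; adjusted p = 0.779 with an estimated correlation). Of these, 7 passed adjusted over the list alone, all higher, including Il7r, Ifngr1 at 1.26 ± 0.14, Emb at 0.96 ± 0.08 and Ms4a4b at 0.80 ± 0.09. The processed signals gave Il7r 2.76.

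T cell receptor signalling components fell as a set, with a median of -0.14 over 29 genes, -0.11 on replicate 1 and -0.23 on replicate 2 (camera adjusted p = 0.0425; adjusted p = 0.779 with an estimated correlation), but the median turned to 0.21 with median centring. The call was also lost with processed signals (median -0.22, camera adjusted p = 0.0556), without the filter on dim probes (-0.14, 0.0596) and without bright genes (-0.18, 0.0784). Settings that kept the call included running-median centring (-0.22, camera adjusted p = 0.0118) and the mean of all kept probes (-0.19, 0.0327). Adjusted over the list alone, 7 passed as lower and 3 as higher, with the costimulatory receptor gene Cd28 at -0.71 ± 0.08, the receptor chain genes Cd3g at -0.61 ± 0.07 and Cd247 at -0.61 ± 0.07, and the adaptor gene Lcp2 at -0.58 ± 0.08. Genes induced by T cell receptor signals at selection did not pass (camera adjusted p = 0.766), with a median of -0.04 but a mean of 0.12 over 19 genes. Their members went both ways: Zbtb7b, the ThPOK gene of CD4 lineage choice, was at least 2.69-fold higher over a control signal not well above background, Runx3 stood at 1.09 ± 0.15 over a control signal well above background on 1 array, Gata3 at 0.65 ± 0.08 and Egr1 at -0.56 ± 0.07.

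Interferon-stimulated genes rose, with a median of 0.09 over 30 genes (camera adjusted p = 0.0317; 0.0667 with median centring), inside the 95% range of genes matched on intensity (-0.11 to 0.10), and so did genes of MHC class I presentation, with 0.18 over 20 (camera adjusted p = 0.0256). Both gave adjusted p = 0.779 with an estimated correlation. Adjusted over the list alone, 4 of the 30 interferon-stimulated genes passed, all higher, with Irf1 at 0.91 ± 0.11 and Zbp1 at 0.62 ± 0.09. In the MHC class I list 7 passed as higher and 1 as lower, with Psmb9 at 0.75 ± 0.11, Tap1 at 0.42 ± 0.08 and H2-Q1 at -0.69 ± 0.10. Ribosomal protein genes rose, with medians of 0.49 and 0.40 over 82 genes (camera adjusted p = 4.38e-17; adjusted p = 0.779 with an estimated correlation), and 63 were higher on both arrays. Adjusted over the list alone, 51 passed as higher and 1 as lower, with Rps16 at 1.83 ± 0.08 and Rpl37a at 1.52 ± 0.08. They are among the brightest genes measured and made up 43.2% of the 95 genes at or above their median intensity. Genes matched on intensity had a median of 0.32, and the ribosomal median lay above their 95% range of 0.19 to 0.43. Few other genes were as bright as the brighter ribosomal genes, so their matches reached down to dimmer genes, whose ratios were lower. That excess therefore does not count against intensity bias. The processed signals gave the ribosomal list a median of 0.16.

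The other lists did not pass. T lineage transcription factors had a median of 0.16 over 34 genes (camera adjusted p = 0.103), which came from replicate 2 (0.27) and not replicate 1 (-0.01). With median centring that list passed (camera adjusted p = 0.0337). Ikzf2, the Helios gene, stood at 1.12 ± 0.08 in it. Cytokine receptor and JAK-STAT genes had a median of 0.05 over 35 genes (camera adjusted p = 0.385), with Il18r1 at 1.37 ± 0.08, or 2.52 from the processed signals, and the signalling inhibitor gene Socs3 at -1.06 ± 0.07. Trafficking and adhesion receptors went both ways, with a median of -0.01 and a mean of 0.12 over 23 genes (camera adjusted p = 0.801). Cd9 was at 1.62 ± 0.15 and Itga6 at -0.81 ± 0.09, and 7 members passed as higher and 7 as lower adjusted over the list alone. BCL2 family and caspase genes had a median of 0.05 and a mean of -0.05 over 28 genes (camera adjusted p = 0.959), with the proapoptotic gene Bbc3 at -1.14 ± 0.08, Fas at -0.86 ± 0.11 and Casp6 at -0.81 ± 0.08. Genes of the p53 response had a median of -0.17 over 20 genes, -0.16 on replicate 1 and -0.06 on replicate 2 (camera adjusted p = 0.119), or 0.07 with median centring, with Zmat3 at -0.57 ± 0.07. SLAM family genes had -0.09 over 9 genes (camera adjusted p = 0.607), or 0.12 with median centring, with Slamf1 at -0.93 ± 0.07. Median centring raised the median of all genes by 0.10 on replicate 1 and 0.16 on replicate 2, so list medians under it sit on a higher baseline. Camera's direction for the p53 and SLAM lists stayed down under it. Lysosome and glycolipid presentation genes had -0.02 over 27 genes (camera adjusted p = 0.662), or 0.20 with median centring. Oxidative phosphorylation genes had 0.02 over 88 genes (camera adjusted p = 0.222) and passed with median centring, at 0.47. Immediate early and heat shock genes had a median of -0.05 and a mean of 0.07 over 16 genes (camera adjusted p = 0.662), or a median of 0.33 with median centring, and Jun stood at 2.05 ± 0.14.

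Markers of other cell types were measured beside these groups. Stromal or endothelial markers rose, with a median of 0.67 over 11 genes (camera adjusted p = 0.00265; 0.0664 with median centring; 0.155 where both channels had to be well above background) and of 0.37 on replicate 1 alone, and Dcn stood at 0.84 ± 0.07. Macrophage or monocyte markers rose, with 0.33 over 15 genes (camera adjusted p = 0.00542; 0.0580 with median centring), and Adgre1 stood at 0.92 ± 0.12. Both lists gave adjusted p = 0.779 with an estimated correlation. B cell markers had a median of -0.21 over 9 genes, -0.44 on replicate 1 and -0.12 on replicate 2 (camera adjusted p = 0.0616) and passed as lower with median centring (0.00661), the mean of all kept probes (0.0451), running-median centring (0.0447) and without bright genes (0.0172). Gamma delta T cell markers had 0.17 over 5 genes (0.348), regulatory T cell markers -0.03 and 0.39 on the 2 arrays over 7 (0.371) and dendritic cell markers -0.01 and 0.30 over 5 (0.662). Granulocyte markers were at -1.54 on replicate 1 and 0.69 on replicate 2 (7 genes, camera adjusted p = 0.348), and erythroid markers at -0.37 and 1.39 (6 genes, 0.797). Thymic epithelial markers were at -0.37 and 0.21 (11 genes, 0.371).

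**Figure D2:**
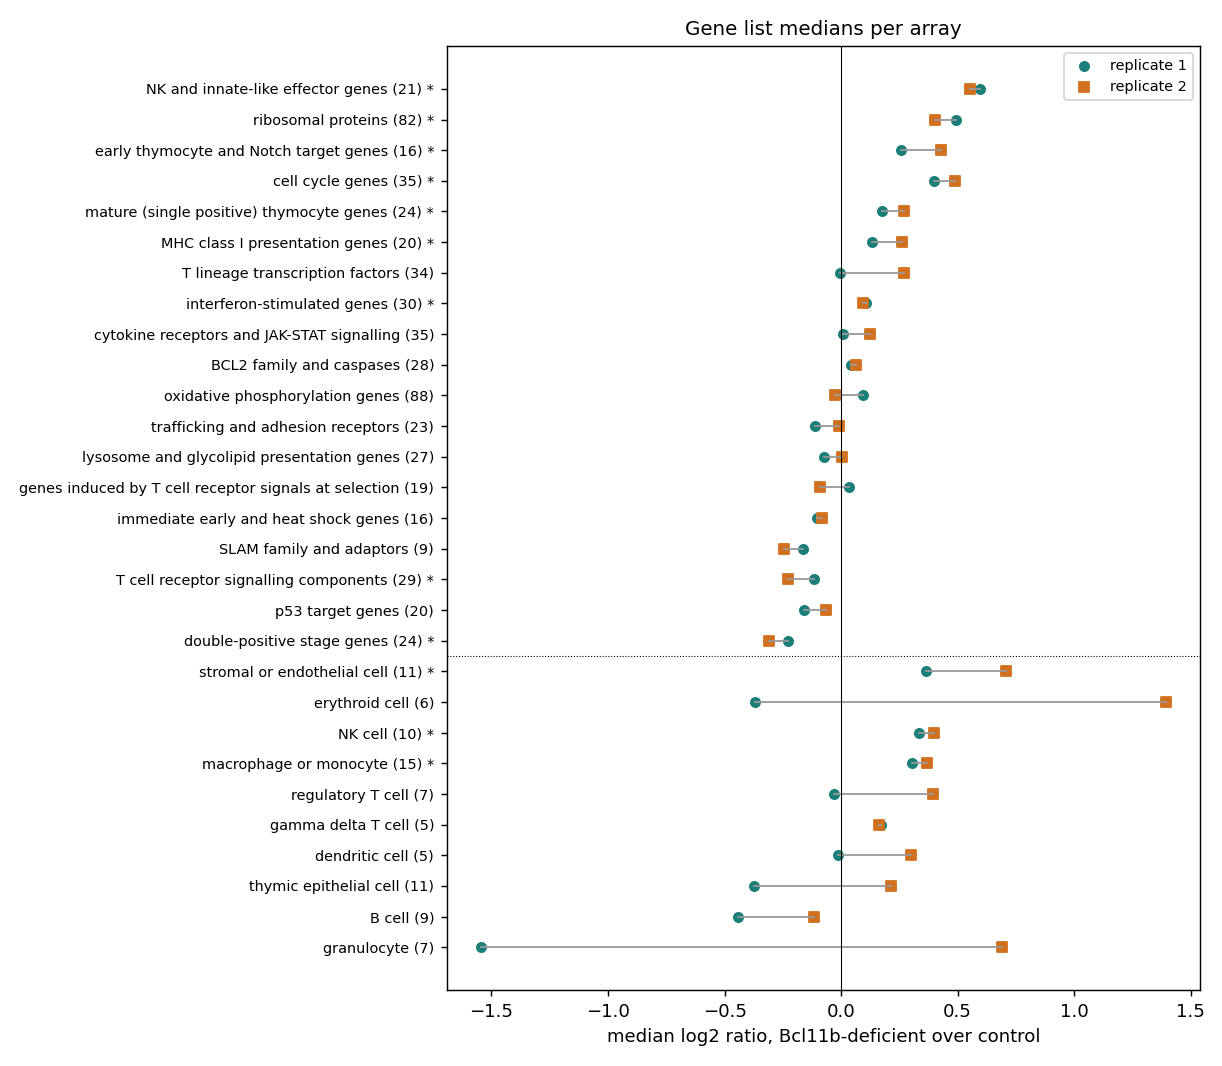
Median log2 ratio of Bcl11b-deficient over control for each gene list on replicate 1 (circles) and replicate 2 (squares), with the number of measured genes in brackets and an asterisk where camera's adjusted p with the preset correlation was under 0.05. Markers of other cell types stand below the dotted line. NK and innate-like genes lie at 0.60 and 0.55, while granulocyte markers lie at -1.54 and 0.69. With median centring the medians of DP stage and T cell receptor signalling genes are above 0. That centring raises the median of all genes by 0.10 and 0.16 on replicates 1 and 2, and camera's direction for the DP stage list stayed down.

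Over all genes, limma called 0 of 14922 at an adjusted p of 0.05, with the smallest at 0.0668. At an unadjusted p of 0.05 there were 4355 genes, 2250 higher and 2105 lower, where chance gives 746.1. Of the other tools, separate-channel limma called 1282 genes, 710 higher and 572 lower, limma on Agilent's processed signals called 213, 111 higher and 102 lower, or 131 with the probes kept unchanged, 74 higher and 57 lower, and limma after median centring called 982, 877 higher and 105 lower. Many genes called with processed signals were dim, such as Olfr406 and Six3 at a mean log2 processed signal of 4.58 and 4.57, and others bright, such as Ptprz1 at 15.96. Feature Extraction put substitutes in place of very dim signals. Calls of dim genes may partly rest on these, which was not tested. By size alone, 163 genes differed at least 2-fold in the same direction on both arrays, 122 higher and 41 lower, and 4 in opposite directions. Processed signals gave 469 such genes, 268 higher and 201 lower, with 14 in opposite directions. Other kept probes of the 163 genes numbered 80. Of these probes, 69 had the same sign as the gene's brightest probe. Only 16 of them were also at least 2-fold changed on both arrays. Of the 122 higher genes, 40 had a mean log2 intensity of at least 16, and none of the 41 lower genes did. Across genes, the log2 ratios of the 2 arrays had a Pearson correlation of 0.67 and a Spearman correlation of 0.63, genes not being independent replicates, and 74.9% of genes had the same sign on both. Since Cy5 marked the deficient cells on both arrays, dye and genotype cannot be separated in any of these values. Ratios of dim genes are compressed: in simulated signals a log2 ratio of 1 came out at 0.51 where the mean log2 intensity was under 10.

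**Figure D3:**
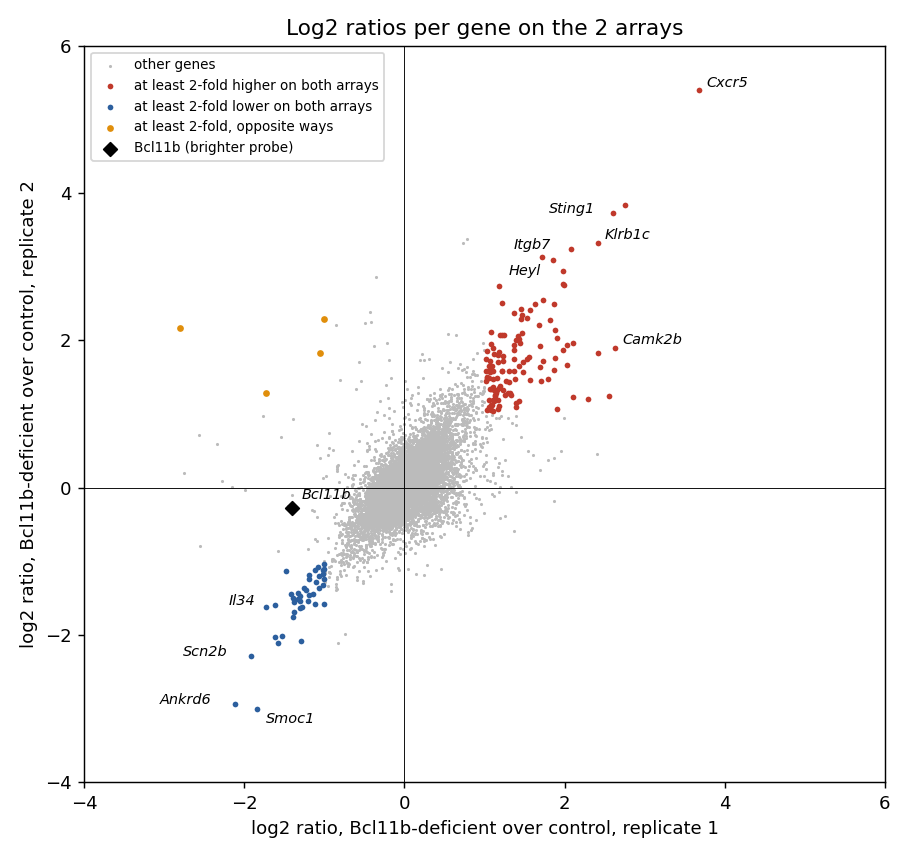
Log2 ratio of Bcl11b-deficient over control for each of 14922 genes on replicate 1 (horizontal) and replicate 2 (vertical). Red and blue points are the 122 genes at least 2-fold higher and the 41 at least 2-fold lower on both arrays, orange points the 4 that differed in opposite directions, and the diamond the brighter Bcl11b probe.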

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

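Running-median centring, removal of bright genes and the other Bcl11b probe were chosen after seeing the data. Among 14922 genes, median centring gave 982 past the threshold (877 higher, 105 lower), separate-channel limma 1282 (710 and 572), Agilent processed signals 213 (111 and 102), or 131 (74 and 57) with the probe of each gene kept, and the value table of the series 124 (70 and 54). The cause was not tested. Median centring and processed signals shared 103 genes. Many genes called with processed signals were dim, where substitutes for very dim signals may shape the ratio. The remaining alternatives that give a test called 0. The 163 genes changed at least 2-fold (122 higher, 41 lower) became 469 (268 and 201) with processed signals, 468 (268 and 200) with the value table and 273 (248 and 25) with median centring, and 110 (85 and 25) without background subtraction and 122 (82 and 40) with running-median centring. They became 549 at 1.5-fold and 34 at 3-fold, and 243 to 449 on a single array, as those rules imply. Leaving out a replicate leaves no test of genes or lists. Calls for 12 lists became 0 with an estimated correlation in camera, which rests on 1 residual degree of freedom, and numbered 8 to 13 under the other alternatives. Median centring moved the median of all genes by 0.10 on replicate 1 and 0.16 on replicate 2, and turned the T cell receptor signalling list to 0.21. The correlation of 0.67 across genes became 0.709 with processed signals, 0.709 with the value table, 0.744 with median centring, 0.660 with no filter, 0.648 with both channels filtered and 0.684 with the mean of probes. It became 0.642 with running-median centring and 0.659 without bright genes. The cause was not tested.

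Bcl11b was lower under every alternative, with adjusted p from 0.0522 to 0.435, and read -1.40 to -0.28 when either replicate was left out. With processed signals the other Bcl11b probe was the brighter one, at -1.75, while the original probe read -0.80. Of the 125 named genes, 4 changed sign under some alternative other than leaving out a replicate, and 7 had the other sign on a single array. Rgs3 read -0.36 with processed signals and -0.36 with the value table, and H2ac10 -0.26 and -0.26. Another probe became the brightest there, and the original probes read 2.75 and 1.66 with processed signals. Bmf turned with median centring and Ciita with running-median centring. Signal over background limited the folds of Rptoros, Cd160, Zbtb7b and 1 probe of Heyl, among others, to bounds, and compressed a simulated log2 ratio of 2 to 1.02 at the lowest intensities.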

Other observations

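Several tests were chosen after the results were seen. They were those of granulocyte and erythroid signals between arrays, of histone genes, of chromosomes and of NK list members absent from the NK marker list. The test of the ribosomal genes against genes of like intensity was also chosen then, as was the rule that set aside the second ribosomal test. Granulocyte genes separated the 2 control samples. The neutrophil genes S100a8 and S100a9 read -2.35 and -2.56 on replicate 1 and 0.59 and 0.72 on replicate 2. Over the 7 granulocyte markers, the control signal was 6.29-fold lower on replicate 2 than on replicate 1 (median log2 -2.65), while the deficient signal differed by 0.54. Erythroid markers differed in both channels, by -1.24 in the control and 0.86 in the deficient cells, and Hbb-bt read -0.35 and 2.86. Thymic epithelial (-1.62 and -0.96), stromal (-1.67 and -1.20), dendritic cell (-1.53 and -1.25) and macrophage or monocyte markers (-0.85 and -0.79) had lower signals on replicate 2 in control and deficient cells alike, whereas NK cell markers differed by -0.04 and -0.09.

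Of the 766 genes tested on chromosome 6, 18 (2.35%) were changed at least 2-fold on both arrays, against 1.03% of genes elsewhere (one-sided Fisher's exact test, adjusted p = 0.0407 over 21 chromosomes). Of these, 6 lay within 5 Mb, namely the NK receptor genes Klrb1a, Klrb1c, Klrc2 and Klrd1 with Cd9 and Spsb2. Neighbouring genes are not independent, so this p is too small to the extent that they move together. A stretch of 5 Mb on chromosome 11 held 5 changed genes, Socs3, Cd7, Fn3k, Rptoros and Sgsh. Stretches with 4 changed genes lay on chromosomes 4, 7 and 9, the last with Cxcr5 and Scn2b. Of 41 histone genes, 19 were higher on both arrays and 8 lower, and their median of 0.13 lay inside the range of genes of like intensity, which reached 0.20.

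Ribosomal protein genes were higher as a set, with a median of 0.45. Intensity bias left by the normalisation may account for much of this, since genes matched on intensity had a median of 0.319. The ribosomal median lay above the 95% range of such draws (0.19 to 0.43), but that excess does not count against intensity bias. Few other genes were as bright as the brighter ribosomal genes, so their matches reached down to dimmer ones. Medians of all genes were 0.22 and 0.25 at a mean log2 intensity of 16 to 17, and 1.06 and 1.07 from 17. After centring on genes of like intensity the lower ribosomal median of the 2 arrays was 0.00312, which met the bound set in advance against an effect of Bcl11b loss. That test was set aside because ribosomal genes made up 43.2% of the 95 genes at or above their own median intensity, so the centring removed part of what it was meant to measure. The 17 ribosomal genes with a mean log2 intensity under 16 had a median of 0.03 (camera adjusted p = 0.714), and dye, intensity and loss of Bcl11b cannot be told apart for these genes.

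NK and innate-like effector genes were higher as a set, with a median of 0.56. Intensity bias is argued against, since matched genes had a median of -0.00215 (95% of draws from -0.13 to 0.14). RNA of NK cells in the deficient samples may contribute and stays open, since 2 of 3 measured genes abundant in NK cells, Tyrobp (0.07 and 0.39) and Fcer1g (0.37 and 1.29), were higher on both arrays and Prf1 (-0.09 and -0.34) was lower. Tyrobp and Fcer1g are also myeloid genes, and macrophage or monocyte (0.33) and stromal markers (0.67) were higher with the list. A direct effect of Bcl11b loss in DP cells also remains open and was not tested apart from the dye or Cre. The 12 list members absent from the NK cell marker list had a median of 0.60. They still belong to a list of NK and innate-like effector genes, so their median does not separate NK cell RNA from an effect in DP cells.

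The 163 genes changed at least 2-fold might reflect DNA of another strain around the targeted gene. Only 0.613% of them, the single gene Degs2, had a probe within 20 Mb of the Bcl11b probe, where 187 genes were measured (one-sided Fisher's exact test, p = 0.875). In that window 0.535% of genes were changed, against 1.11% of other genes, so no excess was seen near Bcl11b. The window held few of the 14813 genes with a position, so its share of the 163 could hardly have been large. That share therefore says little about the source of the changes as a whole. Strain DNA elsewhere remains open, with 6 of the changed genes within 5 Mb on chromosome 6 and 5 within 5 Mb on chromosome 11. Dye and Cre, which follow genotype on both arrays, remain open too.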
